A study of Mus musculus with 120 samples.

How the data were processed

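Small RNA libraries from mouse testis, epididymis, sperm and epididymal vesicles were compared in 7 tables of reads per feature and in tables of base substitutions, for 120 samples. Per the labels' protocols, the mice were fed control diet, tissues were collected at 8 to 12 weeks of age, total RNA was run on a gel and RNA under 40 nt was cloned. Per the submitters' processing notes the genome build was mm10. The aligner and the counting tool were not given in the sources used here.

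Per the file headers, the deposited tables held read counts for ribosomal RNA (rRNA), transfer RNA (tRNA), microRNA, PIWI-interacting RNA (piRNA) and repeats, with no scaling. In 5 of the tables the deposited rows for genes held expected counts, which were not whole numbers and had been estimated by the authors with a tool that is not named. The tables for epididymis tissue and testis tissue had no gene rows. In the substitution tables the authors deposited, per the file headers, read counts for each mature microRNA and, for each kind of substitution, the percent of reads that carried it, averaged over the positions of that base among positions 1 to 18 of the RNA. These percent values were checked by turning them back into read numbers: 99.62% of 2340 values came within 0.02 of a whole number.

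Each library's group came from its labels. For 1 cauda sperm library they disagree, as its title says the mid wash while its wash label and its column in the table say the high wash, and it was used as high wash replicate 4. In those for substitutions, 4 columns were not used here, since their headers name libraries that the labels do not list. Each cauda sperm wash set held 4 libraries: 1 from sperm not washed with lysis buffer, and 1 each from washes with 0.01% SDS and 0.005% Triton, 0.1% SDS and 0.005% Triton, or 0.1% SDS and 0.5% Triton.

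The 45S row also held the reads of the 28S, 18S and 5.8S rows, so library totals were summed without those 3 rows and the rRNA share was 45S plus 5S. The rRNA list kept all 5 rows, so its numbers of members and its list tests count the same reads more than once. In the tables with genes, 27 gene rows whose names a spreadsheet had turned into dates were left out, at most 0.0255% of a library. Expected counts were rounded to whole numbers. Near-identical tRNA copies shared reads, so a tRNA is reported by the sum over the copies of its isoacceptor. A microRNA with several genomic copies is uncertain in the same way. Each piRNA counted here is a row, and rows that differ only in suffix can have near-equal values. In cauda sperm heads pi-Ankrd11.1 and pi-Ankrd11.2 had 1479 and 1492 CPM. Such rows may share reads, so numbers, list tests and shares of piRNAs may count the same reads more than once. Small nucleolar RNAs, long non-coding RNAs and mRNAs are the gene rows of the tables, so in a library of RNA under 40 nt they stand for fragments.

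The comparisons were fitted with edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. Low rows were removed by edgeR's own filter for the design, libraries were scaled by the trimmed mean of M values (TMM), and each row was tested with the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment over all rows tested and a threshold of 0.05. The head and tail comparison in cauda sperm had a term for the wash, and the tissue comparisons had a term for the acid or base chemistry. Log2 fold changes carry standard errors and come from the scaled fit, while means in counts scaled to a common library total (CPM) are plain shares of that total. Differences in the effect between locations were tested as an interaction. The shares of the RNA classes were compared by exact permutation tests, all of them two-sided, with Benjamini-Hochberg adjustment over the classes of a comparison. With 10 libraries a side 100000 random regroupings were used instead, and, chosen after seeing the data, all 7776 regroupings within the enzymes. Intervals for single libraries are 95% exact Clopper-Pearson intervals. They cover counting error only, because PCR copies cannot be told from separate molecules without molecular identifiers. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for these steps.

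The groups, the tests, the gene lists, the rule for the RNAs named in the text and the alternative settings were fixed before the data were examined. The rule named the 10 rows with the largest rise and the 10 with the largest fall among rows that passed and averaged at least 100 CPM in the higher group, with a tRNA isoacceptor named once, and the 4 most abundant members of each list. Of these, those given with values in the report are the first few. In the substitution tables it named the 5 microRNAs with the largest difference per tissue. The 16 lists covered microRNAs of male germ cells (the mir-34/449 family, the X-linked testis cluster and the mir-17-92 family), of epithelium (mir-200 family), of differentiated tissue (let-7), of the epididymis (Hox-cluster, mir-99, mir-100 and mir-125 members, called the Hox list), of muscle, of blood and of endothelium. The others held nuclear tRNAs whose 5′ fragments are abundant in sperm (the sperm tRNA list), all other nuclear tRNAs, rRNA, piRNA, mRNAs of spermatids, mRNAs of the epididymal epithelium and mRNAs of Sertoli and Leydig cells. Lists with at least 3 tested members were tested against the other rows with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the libraries. Limma's fry was run as well and is not reported. Coordinates are those of GENCODE M21 on mm10.

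Whether replicate numbers pair libraries was checked by correlating the deviations of same-numbered libraries from their group means. In the wash sets the 30 correlations ran from 0.0526 to 0.658, 28 of them the best for that library, and every pair with an unwashed library was above 0.1. In caput sperm with and without polynucleotide kinase the 3 correlations ran from 0.105 to 0.186. Both were taken as paired by this check, the pairing coming from the set or sample number in the labels. The main fits still have no term for it, and the number enters only in the alternatives. Kinase in cauda sperm carries sample numbers of the same kind, with correlations of 0.0794 to 0.349, each best with its own number. It was not taken as paired, a choice that this check does not justify. With 2 libraries a group the correlations of a pair of groups are 1 number, so the tissue tables were not decided by it. Within acid and within base they were 0.557 and 0.563 for kinase against untreated epididymis, 0.225 and 0.315 for AlkB in testis and 0.188 and 0.528 for RppH there. The main tissue fits have no term for the number. Between acid and base the untreated libraries had −0.464 in epididymis and 0.285 in testis. These values bear on acid against base and not on the enzymes within 1 chemistry, where pairing stays possible. Tails and whole sperm of the cauda in the hypotonic wash had 3 correlations of 0.262 to 0.421, but they were not compared.

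The scripts were tested on data simulated from real means and library sizes with 200 rows changed. This does not test shifts of scale. In the high wash, 65.3% of 2-fold and 91.8% of 4-fold changes were recovered, and 4.97% of calls were false. For cauda heads against tails the shares were 1.12% and 45.3%. For kinase they were 26.5% and 92.0% in cauda sperm, 35.5% and 89.5% in epididymis and 10.1% and 50.0% in testis. For epididymosomes against cauda sperm they were 0% and 47.6%, and for the fusion 4.82% and 38.9%, with 6.98% and 9.30% of calls false.

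The alternatives were size factors from the median of ratios (RLE), library totals alone, no filter on low rows, rRNA rows left out, tRNA copies summed, DESeq2 1.42.0 in place of edgeR, replicate numbers as a block, only 1 wash or chemistry, the title suffix as a term, class shares without rRNA in the denominator or, where numbers pair libraries, tested within them, and each library left out in turn. Cauda sperm libraries of the maturation series with the same source number were also summed. Substitution results were recomputed as means, with each mature RNA counted once, and over RNAs with at least 1000 reads in all 6 libraries. Library depth is given per table in the report, and the spread between libraries of a group was far larger than the counting error of these totals. Genome alignments and sequence positions of tRNA or piRNA fragments were not analysed here, since the tables give 1 number per feature.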

Results

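Small RNA under 40 nt was sequenced from mouse testis, epididymis, sperm and epididymosomes, the vesicles of the epididymal fluid. Cauda sperm were sequenced unwashed and after 3 detergent washes (n = 5 each, 3292715 to 13267381 reads). Whole sperm, heads and tails came from the cauda epididymis (n = 6, 3 and 4) and the testis (n = 2, 3 and 2), with 5749838 to 56011165 reads. Cauda and caput sperm were cloned with and without polynucleotide kinase, which repairs RNA ends (n = 3 each, 156347 to 2533459 reads). Cauda epididymis and testis tissue were cloned untreated or after 4 enzymes, each with 2 libraries labelled acid and 2 labelled base, at 536488 to 19566143 and 228043 to 14664480 reads. A series along maturation held cauda sperm (n = 7), testicular sperm (n = 4), cauda epididymosomes (n = 3), mock-fused testicular sperm (n = 2) and 4 single libraries, at 4842247 to 22190674 reads. The titles of the 4 testicular sperm libraries each carry a different mark (2X, NaCl, fusion untreated or somatic). These libraries were pooled as a group all the same, so they may differ in preparation. Testicular sperm fused with caput epididymosomes (n = 2) were set against the mock fusion, at 9719319 to 15998693 reads. Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, errors of log2 fold changes are standard errors, and those of shares are SD. In the maturation series 6 of the 7 cauda sperm titles carry 3 source numbers, each at 2 ages, and the labels do not say what the number marks. Except where a set number is given, nothing else in the labels says that libraries of a group came from separate animals, so the p values measure the spread between libraries. A rise or fall of a list is the number of members that passed, and list tests were set against other RNAs with camera.

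The low wash asked which RNAs of cauda sperm are removed by mild detergent. Mir451a, a microRNA of red blood cells at chromosome 11, 78073170 to 78073241 (mm10), fell by 4.75 ± 0.69 (log2, n = 5 and 5, adjusted p 0.00318), from 235.8 to 8.71 CPM. Mir486, another red cell microRNA, fell by 4.56 ± 0.63 (adjusted p 0.000881), and Mir141, of the epithelial mir-200 family, fell by 2.54 ± 0.43 (adjusted p 0.00693). All microRNAs together were 15.1% ± 2.83 of reads in unwashed sperm and 5.12% ± 1.2 after the wash, with no overlap (exact p 0.00794, adjusted over the classes 0.0476). The tRNA share was 45.5% ± 3.64 and 55.8% ± 6.07 (exact p 0.0238, adjusted 0.0714), and without low wash replicate 3 the difference of 12.4 points passed. The rRNA share was 21% ± 3.82 and 20.3% ± 5.21 (exact p 0.786). These tests permute all 10 libraries freely. Tested within the 5 sets by sign changes, a choice made after seeing the data, the smallest possible exact p is 0.0625, so no share can pass at any wash, and the microRNA share fell in all 5 sets at each wash. Of 12617 RNAs tested 9 fell and 0 rose (unadjusted p under 0.05 for 400 higher, and 61 calls by DESeq2). In the lists 3 of 7 blood microRNAs fell (6 adjusted over the list alone), 1 of 5 mir-200 microRNAs (5), and 0 of 12 let-7 (12) and 0 of 11 Hox list microRNAs (11). Those 4 list tests held with an estimated correlation (adjusted p 0.000668, 0.00557, 0.0268 and 0.00557). With the set number as a block 92 RNAs rose and 209 fell, among them 5 mir-200, 12 let-7, 10 Hox list, 6 blood, 3 muscle and 1 mir-17-92 microRNA.

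The mid wash had 10 times the SDS of the low wash, at the same Triton. Fragments of Snord52, a small nucleolar RNA and guide of rRNA modification at chromosome 17, 34950952 to 34951017, fell by 4.74 ± 0.37 (adjusted p 6.84e-09), from 114.8 to 5.88 CPM (n = 5 and 5). Small nucleolar RNAs were not tested as a list. Mir451a fell by 5.94 ± 0.73 and Mir141 (−3.98), while Tbrg3 fragments rose by 0.93 ± 0.25 (adjusted p 0.0446) and those of Git1, a GTPase regulator, by 1.21 ± 0.33 (adjusted p 0.0482). The microRNA share was 4.57% ± 1.53 and the rRNA share 13.6% ± 2.53, both without overlap with unwashed sperm (exact p 0.00794, adjusted 0.0238). For tRNA the share was 55.6% ± 7.73 (exact p 0.0397, adjusted 0.0794), and it passed without mid wash replicate 5, at a difference of 13.5 points. In all 88 RNAs rose and 264 fell, 120 of the falls among 322 microRNAs. Falls were made by 5 of 5 mir-200 microRNAs, 9 of 12 let-7 (12 adjusted over the list alone), 9 of 11 Hox list (11), 6 of 7 blood (7), 2 of 8 mir-17-92 (3), 0 of 4 muscle (4), 0 of 3 mir-34 (2), 0 of 2 endothelial (2) and 1 of 5 rRNA members (3). The first 4 list tests held with an estimated correlation, at 0.0237 or below, and muscle was lost (adjusted p 0.0562), as was rRNA (0.11). With the set block 920 RNAs rose and 821 fell, with 11 X-linked, 7 mir-17-92 and 12 let-7 microRNAs lower, and the rRNA, muscle and mir-17-92 tests reached p of 0.0104, 0.00164 and 0.0219 with an estimated correlation. Library totals alone moved the median by 0.45 and turned the split to 885 higher and 216 lower, and DESeq2 gave 286 and 357. Without unwashed replicate 4 the calls numbered 233.

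The strongest wash, with more Triton, was set against unwashed sperm to ask what more it removed. Snord52 fell by 4.82 ± 0.37 (adjusted p 7.71e-09), Snord2 (−4.11 ± 0.44), Mir451a (−4.51 ± 0.68) and Mir141 (−3.48, n = 5 and 5). For microRNA the share was 4.90% ± 1.73 and the rRNA share 13.1% ± 1.60 (both exact p 0.00794, adjusted 0.0238), the tRNA share was 56.7% ± 7.02 (exact p 0.0238, adjusted 0.0476), and the piRNA share was 12.1% against 7.79% (exact p 0.119). Within sets it was higher in 5 of 5 at the mid and at the high wash, by 4.99 and 4.33 points, with exact p of 0.0625, the smallest possible. The tRNA call was lost without any 1 of 7 libraries (high wash 1, 2 and 4, unwashed 1, 3, 4 and 5), at differences of 8.60 to 11.9 points. In all 15 RNAs rose and 184 fell, with 4 of 5 mir-200 microRNAs (5 adjusted over the list alone), 7 of 12 let-7 (12), 8 of 11 Hox list (11), 5 of 7 blood (7), 1 of 8 mir-17-92 (3), 0 of 4 muscle (4) and 1 of 5 rRNA members (3) lower. List tests for the first 4 held with an estimated correlation (0.0279 or below). No member of the sperm tRNA, spermatid or epididymal mRNA lists passed. With the set block 501 RNAs rose and 600 fell, and 8 X-linked, 7 mir-17-92, 12 let-7 and 4 muscle microRNAs were lower, with estimated-correlation p of 0.0139 for mir-17-92, 0.00171 for muscle and 0.00752 for rRNA. Library totals alone, with a median shift of 0.43, gave 166 higher and 172 lower. Leaving out unwashed replicate 4 left 122 calls.

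**Figure D1:**
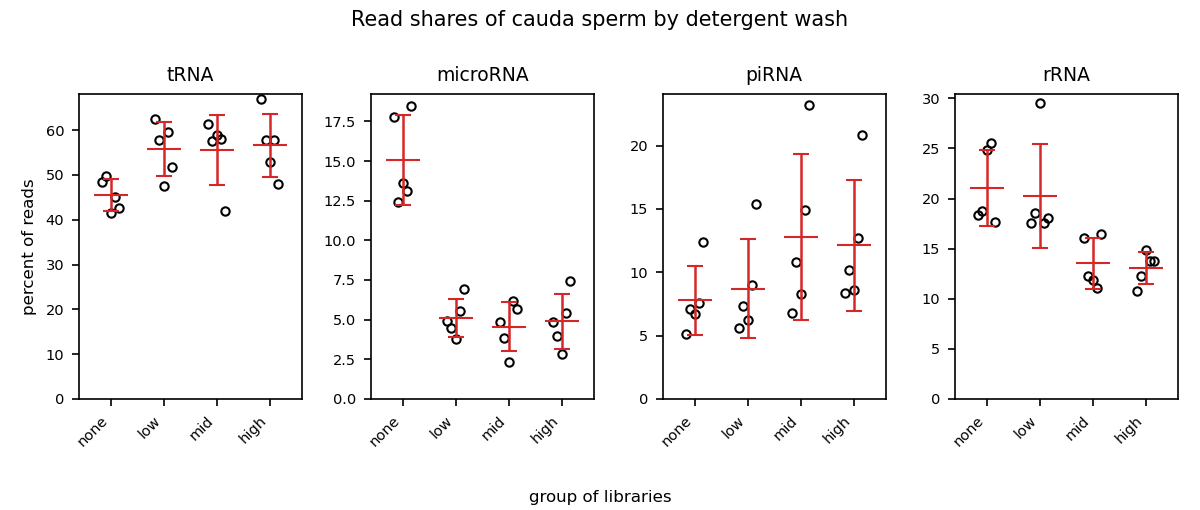
Share of reads (percent of the library) taken by each RNA class in cauda sperm, by wash. Points are libraries and bars are means with SD, n = 5 per wash, and the microRNA share of the unwashed libraries, 12.4 to 18.5%, lies above those of all washed libraries.

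Heads and tails of cauda sperm were compared to place small RNAs within the cell. Fragments of Plb1, a phospholipase gene at chromosome 5, 32232708 to 32366520, were higher in heads by 4.78 ± 0.52 (log2, adjusted p 8.21e-07, n = 3 and 4), at 130.7 against 5.52 CPM. The piRNAs named pi-Ankrd11.1 were higher by 3.89 ± 0.62, and tRNA His-GTG by 1.89 ± 0.68 (summed over copies, adjusted p 0.0407). Lower in heads were Gm20594 (−4.15 ± 0.61) and the RNA component of RNase MRP (Rmrp, −3.12 ± 0.54). The piRNA share was 4.04% ± 1.14 in heads and 21.7% ± 5.0 in tails, and microRNA 2.76% ± 0.85 and 8.37% ± 0.93, both without overlap (exact p 0.0286, the smallest possible, adjusted 0.0857). The tRNA share was 72.3% ± 3.39 and 50.5% ± 12.7 (exact p 0.0857). In heads 1200 RNAs were higher and 2340 lower. Of 460 piRNAs 290 were lower and 5 higher (310 and 5 adjusted over the list alone), and 11 of 12 let-7 (12), 8 of 20 X-linked, 7 of 11 Hox list (10), 2 of 5 mir-200 (5), 3 of 7 blood (6), 3 of 4 muscle microRNAs and 4 of 13 spermatid mRNAs were lower. The let-7, other tRNA and piRNA tests passed at the preset correlation and were lost with the estimated one (lowest p 0.203). RLE scaling moved the median by 0.53 and gave 1584 higher and 1115 lower, and DESeq2 gave 1634 and 1094.

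In testicular sperm, heads against tails (n = 3 and 2) gave 0 calls by edgeR, with an unadjusted p under 0.05 for 104 higher and 237 lower RNAs, and 27 higher and 11 lower by DESeq2. The titles share a letter between 2 heads and 2 tails, and with the letter as a block 43 RNAs were higher and 60 lower. The shares cannot reach 0.05 in this design, whose smallest exact p is 0.1. The microRNA share was 1.52% ± 0.35 in heads and 4.27% ± 0.33 in tails, and rRNA 20.9% ± 10.2 and 4.55% ± 1.5 (exact p 0.1 and 0.2). Adjusted over the list alone, 3 of 4 mir-34 microRNAs, which mark meiotic and later germ cells, were lower in heads, with 13 of 20 X-linked, 8 of 9 mir-17-92, 4 of 12 let-7 and 6 of 7 blood microRNAs, and 4 of 5 rRNA members were higher. Those of mir-34, X-linked, mir-17-92, blood and rRNA held with an estimated correlation (adjusted p 0.0227, 0.0382, 0.0265, 0.00406 and 0.00406), and let-7 was lost (0.0718). The piRNA list had a median of −0.01 but a mean of 0.09 and an upward test (adjusted p 0.00253), lost with the estimated correlation (adjusted p 0.744). Without head replicate 3 there were 4 calls.

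Whole sperm of the cauda epididymis were set against whole testicular sperm to follow RNA through the epididymis. Cd52, a surface protein gene of the epididymis at chromosome 4, 134082448 to 134095082, was higher in cauda sperm by 9.36 ± 1.70 (log2, adjusted p 0.000251, n = 6 and 2), and Crisp1, a secreted epididymal protein gene, by 7.11 ± 1.65. Mir205 was higher by 6.93 ± 1.53, Mir10a by 6.50 ± 1.26 and tRNA Val-AAC by 5.74 ± 0.94. Mir7234 was lower (−5.27). For piRNA the share was 9.67% ± 3.18 against 77.6% ± 8.01 and the tRNA share 56.4% ± 10.5 against 5.77% ± 3.22 (exact p 0.0357, the smallest possible, adjusted 0.0714). In all 1773 RNAs were higher and 2660 lower. Among the lists 311 of 460 piRNAs were lower and 3 higher (318 and 7 adjusted over the list alone), 5 of 6 Sertoli and Leydig mRNAs lower, and 5 of 5 epididymal mRNAs, 5 of 5 mir-200, 10 of 12 let-7, 8 of 11 Hox list (9), 4 of 4 muscle and 6 of 7 blood microRNAs, 6 of 9 sperm tRNAs and 15 of 42 other tRNAs higher. With an estimated correlation all list tests were lost (lowest p 0.06). The cauda libraries were of both washes and the testis libraries of the detergent wash. RLE scaling, with a median shift of 0.31, gave 2261 higher and 2136 lower, DESeq2 2381 and 2117, and without testis whole sperm replicate 3 the calls numbered 2887.

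Whether the head to tail difference itself differed between cauda and testis was tested as an interaction. The piRNAs pi-Ankrd11.1 and pi-Ankrd11.2 had a head to tail difference higher in cauda by 3.81 ± 0.91 and 3.74 ± 0.92 (log2, adjusted p 0.00731 and 0.00841, n = 6 heads and 6 tails). For Smcp, a spermatid mRNA of the sperm mitochondrial capsule at chromosome 3, 92583867 to 92588997, it was lower (−4.54 ± 0.67), for Gm20594 (−4.09 ± 0.86) and for the piRNA 1-qD-2017.1 (−3.68 ± 0.64). It differed upward for 633 RNAs and downward for 1071, with 246 of 460 piRNAs lower and 3 higher (278 and 3 adjusted over the list alone), 3 of 5 rRNA members (4) and 4 of 13 spermatid mRNAs lower and 2 of 42 other tRNAs higher. None of the microRNA lists had a member that passed. List tests of the piRNAs and of both tRNA lists were lost with the estimated correlation (lowest p 0.177). All testis heads and tails were of the detergent wash and 5 of the 7 cauda ones were hypotonic, and the term for the wash rests on cauda libraries alone, so location and preparation are only partly separated. RLE scaling gave 825 and 346 with a median shift of 0.50, and DESeq2 866 and 551. The count fell to 155 without testis tail replicate 1, to 1033 without testis tail replicate 2 and to 1102 without cauda head hypotonic replicate 2.

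Polynucleotide kinase was added to cauda sperm RNA to bring in fragments whose ends block cloning. Snord82, a small nucleolar RNA at chromosome 1, 86356261 to 86356330, rose by 6.45 ± 0.49 (log2, adjusted p 2.41e-10, n = 3 and 3), from 10.9 to 702.2 CPM. Snord88c rose by 5.26 ± 0.41, 28S rRNA by 4.16 ± 0.48 and the nuclear RNA Malat1 by 4.13 ± 0.45. Falls were led by Mir30c-1 (−4.72 ± 0.42), Mir183 (−4.66 ± 0.47) and Mirlet7b (−4.14 ± 0.47). The rRNA share was 63.6% ± 11.4 with kinase and 7.13% ± 1.51 without, tRNA 30.7% ± 10.2 and 74.6% ± 4.80, and microRNA 2.29% ± 0.97 and 14.4% ± 2.77 (exact p 0.1, the smallest possible). In all 486 RNAs rose and 429 fell. Members that fell were 16 of 16 X-linked, 8 of 8 mir-17-92, 5 of 5 mir-200, 12 of 12 let-7, 10 of 10 Hox list and 6 of 6 blood microRNAs and 5 of 9 sperm tRNAs, and rises by 5 of 5 rRNA members. Of 37 other tRNAs 5 rose and 10 fell, and of 404 piRNAs 92 rose and 127 fell, which library totals alone turned to 16 and 163. None of the list tests held with an estimated correlation (lowest adjusted p 0.0855). With library totals alone, a median shift of −0.49, 323 RNAs rose and 509 fell.

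The same treatment of caput sperm RNA raised Lcn8, a lipocalin gene of the epididymal epithelium at chromosome 2, 25653120 to 25656217, by 3.99 ± 0.45 (log2, adjusted p 8.78e-07, n = 3 and 3). Tbrg3 rose by 3.60 ± 0.56 and the nuclear RNA Neat1 by 2.93 ± 0.44. Mirlet7b fell by 4.66 ± 0.47, Mir532 (−4.54 ± 0.61) and Mir183 (−4.20 ± 0.45). For microRNA the share was 5.08% ± 2.00 with kinase and 35.3% ± 1.48 without, and rRNA 58.4% ± 8.81 and 26.6% ± 6.64 (exact p 0.1, the smallest possible), while tRNA was 29.5% and 30.1% (exact p 1.0). In all 192 RNAs rose and 403 fell. Falls were made by 12 of 12 let-7, 8 of 8 mir-17-92, 5 of 5 mir-200 and 9 of 10 Hox list microRNAs, 4 of 6 blood microRNAs and 17 of 37 other tRNAs (18 adjusted over the list alone). The X-linked microRNAs went both ways, with 5 of 16 higher and 3 lower (5 and 5), at a median of −0.53, and piRNAs too, with 57 of 404 higher and 126 lower, at a median of −0.11 that RLE scaling turned to 0.36. No list test held with an estimated correlation (lowest adjusted p 0.145). RLE scaling moved the median by 0.46 and gave 376 higher and 320 lower, and DESeq2 306 and 284.

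Cauda sperm were compared with caput sperm, without kinase, to follow sperm along the epididymis. Mir451a was higher in cauda sperm by 5.99 ± 0.45 (log2, adjusted p 2.15e-10, n = 3 and 3), Mir881, of the X-linked testis cluster at chromosome X, 66801944 to 66802021, by 3.92 ± 0.41, and Mir34b by 3.90 ± 0.38. tRNA Thr-AGT was higher by 5.21 ± 0.85 and Val-CAC by 3.14 ± 0.48, summed over copies. Gpx5, a glutathione peroxidase gene of the caput epithelium at chromosome 13, 21286429 to 21292731, was lower (−9.49 ± 0.73), Mir204 (−6.43 ± 0.48) and Mir146b (−5.41 ± 0.49). For tRNA the share was 74.6% ± 4.80 against 30.1% ± 6.18, microRNA 14.4% against 35.3% and rRNA 7.13% against 26.6% (exact p 0.1, the smallest possible). In all 264 RNAs were higher and 501 lower. Higher were 16 of 16 X-linked and 3 of 3 mir-34 microRNAs, 5 of 6 blood microRNAs, 6 of 8 mir-17-92, 8 of 9 sperm tRNAs and 22 of 37 other tRNAs. Lower were 9 of 12 let-7 microRNAs, 9 of 10 epididymal mRNAs and 111 of 404 piRNAs (97 adjusted over the list alone). Of the list tests the X-linked one held with an estimated correlation (adjusted p 0.0424), and mir-34 had 0.0833. Library totals alone, with a median shift of −0.70, gave 157 higher and 742 lower.

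The same locations were compared with kinase. Crisp1, at chromosome 17, 40293758 to 40319207, was higher in cauda sperm by 7.44 ± 0.66 (log2, adjusted p 3.43e-09, n = 3 and 3), and Mir204 was lower (−8.13 ± 0.59). Snord88c was higher by 5.82 ± 0.48, and tRNA Val-CAC by 3.10 ± 0.47. Gpx5 was lower (−8.11 ± 0.68) and Lcn8 (−8.02 ± 0.66). The tRNA share was 30.7% against 29.5% (exact p 1.0) and rRNA 63.6% against 58.4% (exact p 0.6). In all 304 RNAs were higher and 261 lower. Of the other tRNAs 27 of 37 were higher (30 adjusted over the list alone), with 6 of 9 sperm tRNAs, 5 of 6 blood and 3 of 3 mir-34 microRNAs. The X-linked microRNAs went both ways, 5 of 16 higher and 5 lower, and 6 of 10 epididymal mRNAs and 82 of 404 piRNAs were lower, with 1 and 23 higher. With an estimated correlation all list tests were lost (lowest p 0.00903, adjusted 0.117). RLE scaling, with a median shift of −0.25, gave 261 higher and 360 lower, and library totals, with −1.26, 138 and 743.

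Whether the response to kinase differed between cauda and caput sperm was tested as an interaction. It was higher in cauda sperm for Snord88c by 4.95 ± 0.72 (log2, adjusted p 5.06e-05, n = 6 and 6), for Snord32a by 4.47 ± 0.57, for Crisp1 by 4.03 ± 0.97 and for Clu, a gene of Sertoli cells and epididymis, by 3.77 ± 0.72. For Mir465b-1, at chromosome X, 66829202 to 66829280, it was lower (−5.20 ± 0.59), for Mir465c-2 (−4.99 ± 0.57) and for Mir470 (−3.88 ± 0.50). For tRNA Glu-CTC it was lower (−2.81 ± 0.73, summed, adjusted p 0.026). In all 110 RNAs differed upward and 27 downward. The X-linked list had 6 of 16 members lower (9 adjusted over the list alone), and its test held with an estimated correlation (adjusted p 0.0277). Of 5 rRNA members 3 were higher and of 9 sperm tRNAs 2 lower, and both tests were lost with the estimated correlation (adjusted p 0.272 and 0.678). RLE scaling gave 73 and 32 with a median shift of −0.30, library totals 45 and 37 with −0.55, and DESeq2 54 and 34. Without caput kinase replicate 1 the calls numbered 72, without caput kinase replicate 2 there were 71, and without caput untreated replicate 3 there were 84.

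In cauda epididymis tissue, kinase was used to bring in RNAs whose ends block cloning. tRNA Leu-CAG rose by 4.23 ± 0.56 (summed, adjusted p 1e-06, n = 4 and 4), Leu-CAA by 4.21 ± 0.57 and Mir690 by 4.62 ± 0.45. Mir141, an epithelial microRNA at chromosome 6, 124717914 to 124717985, fell by 3.68 ± 0.67, Mir200c (−3.39 ± 0.59) and Mir221 (−3.21 ± 0.69). The microRNA share was 28.8% ± 11 with kinase and 77.9% ± 6.03 without, rRNA 29.5% ± 7.41 and 6.92% ± 0.92, and tRNA 40.5% ± 10.2 and 14% ± 4.88 (exact p 0.0286, the smallest possible, adjusted 0.0357). In all 476 RNAs rose and 271 fell. Rises were made by 25 of 38 other tRNAs, 4 of 9 sperm tRNAs, 5 of 5 rRNA members and 232 of 450 piRNAs, of which 79 fell (83 adjusted over the list alone). Members that fell were 14 of 15 X-linked, 5 of 5 mir-200, 9 of 12 let-7, 10 of 11 Hox list (11), 6 of 7 blood, 5 of 8 mir-17-92 and 3 of 4 muscle microRNAs. None of the list tests held with an estimated correlation (lowest p 0.09).

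Kinase lacking its 3′ phosphatase adds 5′ phosphates only. In epididymis it raised the piRNA pi-Zdhhc23.1 by 6.02 ± 0.47 (log2, adjusted p 1.22e-09, n = 4 and 4), from 0.565 to 100.6 CPM. Mir136 fell by 7.93 ± 0.75, Mir301 (−7.74 ± 0.92) and Mirlet7f-1 (−7.13 ± 0.81). The piRNA share was 8.03% ± 3.33 against 1.18% ± 0.36 untreated, rRNA 52.0% ± 18 against 6.92%, microRNA 37.7% ± 17.4 against 77.9% and tRNA 2.12% ± 1.2 against 14% (exact p 0.0286, adjusted 0.0286). The piRNA call was lost without any 1 of the 4 untreated libraries (differences of 6.74 to 6.95 points) and the tRNA call without any 1 of the 4 treated ones (−12.4 to −11.6). In all 388 RNAs rose and 546 fell. Of 450 piRNAs 335 rose and 6 fell (332 and 6 adjusted over the list alone), and that test held with an estimated correlation (adjusted p 0.000453). Falls were made by 37 of 38 other tRNAs, 9 of 9 sperm tRNAs, 15 of 15 X-linked, 12 of 12 let-7, 5 of 5 mir-200, 9 of 11 Hox list and 6 of 7 blood microRNAs, and these tests were lost (lowest p 0.079).

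AlkB, which removes methyl groups that stop reverse transcription, raised tRNA Met-CAT in epididymis by 1.66 ± 0.51 (summed, adjusted p 0.0121, n = 4 and 4). Fragments of the retroviral repeat MERV1_I rose by 3.38 ± 0.53 and Mir10b, at chromosome 2, 74726070 to 74726137, by 2.78 ± 0.71. Mir301 fell by 4.07 ± 0.71 and Mir221 (−3.81 ± 0.71). For piRNA the share was 0.513% ± 0.183 against 1.18% ± 0.36 and rRNA 4.91% ± 1.10 against 6.92% ± 0.92 (exact p 0.0286, adjusted 0.0476), and both calls were lost without any 1 of the libraries except acid untreated replicate 1, at differences of −0.773 to −0.565 and −2.32 to −1.52 points. For microRNA the share was 87.3% ± 3.16 against 77.9% and tRNA 7.28% ± 1.98 against 14% (exact p 0.0571), and both passed without acid untreated replicate 1, at 11.7 and −8.53 points. In all 173 RNAs rose and 193 fell. Of 38 other tRNAs 15 rose and 8 fell (17 and 8 adjusted over the list alone) and of 450 piRNAs 57 rose (26), which library totals alone turned to 1 and 16 and to 5 and 161. Members that fell were 7 of 15 X-linked (8), 6 of 8 mir-17-92, 4 of 5 mir-200, 5 of 7 blood and 2 of 12 let-7 microRNAs. None of the list tests held with an estimated correlation (lowest p 0.188). Library totals, with a median shift of −1.31, gave 35 higher and 537 lower.

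RppH, which trims 5′ caps and triphosphates, lowered tRNA Val-CAC in epididymis (−4.66 ± 0.63, summed, adjusted p 1.56e-06, n = 4 and 4), as well as Lys-CTT (−4.18 ± 0.56). Mir221 fell by 4.36 ± 0.75, and Mir10b rose by 2.86 ± 0.72 and Mir182 by 2.24 ± 0.75. The piRNA 5-qF-4633.2 rose by 0.81 ± 0.31 (adjusted p 0.0466), with acid libraries alone its value was −0.16, and with the replicate number as a block it did not pass. The microRNA share was 88.0% ± 8.74 against 77.9% (exact p 0.143) and tRNA 6.27% ± 6.64 against 14% (exact p 0.143). In all 25 RNAs rose and 338 fell. Falls were made by 30 of 38 other tRNAs (35 adjusted over the list alone), 6 of 9 sperm tRNAs, 8 of 15 X-linked, 6 of 8 mir-17-92, 4 of 5 mir-200 and 5 of 11 Hox list microRNAs. Of 450 piRNAs 17 rose (0), a test that held with an estimated correlation (adjusted p 0.00173), though with library totals the list's median was −0.08 and 0 rose. The test of other tRNAs was lost (adjusted p 0.062). RLE scaling moved the median by 0.52 and gave 216 higher and 305 lower, and DESeq2 gave 246 and 299.

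Base against acid libraries of epididymis (n = 10 and 10) tested whether the chemistry mattered. The copies of tRNA Arg-CCT include 1 on chromosome 11 that rose by 1.63 ± 0.31 (log2, adjusted p 0.0208), the 1 call of 1 RNA, named after its value was seen. Summed over the copies Arg-CCT did not pass (0.86 ± 0.26, adjusted p 0.982), and with copies summed there were 0 calls, so nothing is read from it. DESeq2 gave 3 calls. No class share passed, with microRNA at 61.7% ± 32.4 and 66.1% ± 23.8 (permutation p 0.728 over all 20 libraries). Regrouped within each enzyme, a choice made after seeing the data, the p was 0.392, and lowest for rRNA (7.22 points, p 0.0468, adjusted 0.234). The call was lost without acid untreated replicates 1 or 2, base untreated 1, base kinase 1 or acid kinase 2. There were 2 calls without acid phosphatase-free kinase 1, acid AlkB 2, base phosphatase-free kinase 2 or base RppH 2, and 3 without acid RppH 1 or 2, base AlkB 1 or base RppH 1. No list member passed, and the let-7, Hox list, muscle, blood and piRNA tests, which passed at the preset correlation, were lost with the estimated one (lowest p 0.0641).

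In testis tissue kinase raised tRNA Leu-CAA by 5.74 ± 1.23 (summed, adjusted p 0.0143, n = 4 and 4), Val-TAC by 5.82 ± 1.47 and 28S rRNA, while Mir449a, of the germ cell mir-34 family at chromosome 13, 113037534 to 113037624, fell by 1.45 ± 0.40 (adjusted p 0.0225). The sums for Val-CAC and Val-AAC did not pass (adjusted p 0.227 and 0.22). The piRNA share was 80.0% ± 12.1 against 90.9% ± 0.49 untreated, rRNA 10.2% ± 9.26 against 1.23% ± 0.32 and tRNA 4.58% ± 3.71 against 0.528% ± 0.283 (exact p 0.0286, adjusted 0.0476). These 3 calls were lost without any 1 of the 4 untreated libraries, at −11.1 to −10.7, 8.83 to 9.06 and 3.99 to 4.19 points, and the microRNA share passed without base kinase replicate 2, at −2.67. Without base kinase replicate 1 the 3 differences were −4.94, 4.29 and 2.25 points. In all 120 RNAs rose and 3 fell, with 5 of 5 rRNA members, 4 of 37 other tRNAs (12 adjusted over the list alone) and 0 of 9 sperm tRNAs (3) higher. No list test held with an estimated correlation (adjusted p 0.0881 for rRNA). Library totals gave 25 higher and 5 lower, and DESeq2 109 and 30. The calls numbered 73 without acid untreated 1, 53 without acid untreated 2, 46 without base untreated 2, 79 without acid kinase 1 and 68 without base kinase 1.

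Kinase without the phosphatase raised 5S rRNA in testis by 6.75 ± 0.60 (log2, adjusted p 1.08e-07, n = 4 and 4), tRNA SeC by 5.71 ± 1.29 and Mir2137 by 5.61 ± 0.95. Mir449a fell by 5.88 ± 0.49, Mir34c, at chromosome 9, 51103034 to 51103110 (−4.62 ± 0.43), and Mir463 (−4.51 ± 0.47). For microRNA the share was 2.53% ± 0.88 against 7.27% ± 0.46, rRNA 31.2% ± 15.5 against 1.23% and piRNA 65.8% ± 14.7 against 90.9% (exact p 0.0286, adjusted 0.0476). In all 257 RNAs rose and 199 fell. Members that fell were 4 of 4 mir-34, 18 of 19 X-linked, 7 of 8 mir-17-92, 12 of 12 let-7 and 3 of 4 muscle microRNAs (4 adjusted over the list alone). The first 3 tests held with an estimated correlation (adjusted p 0.00485, 0.0439 and 0.00485), and let-7 was lost (0.0875). The upward tests of rRNA and piRNA passed at the preset correlation and were lost as well (adjusted p 0.0875 and 0.547). Of 458 piRNAs 179 rose and 16 fell (179 and 18), which library totals alone turned to 107 and 163 and rRNA-free shares to a difference of 3.74 points. With library totals, a median shift of −0.92, 159 RNAs rose and 407 fell.

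AlkB in testis raised Mir184, at chromosome 9, 89802260 to 89802328, by 3.33 ± 0.53 (log2, adjusted p 0.000302, n = 4 and 4), Mir10b by 2.74 ± 0.67 and 5S rRNA by 2.57 ± 0.49. Mir34c fell by 3.53 ± 0.41, Mir463 (−3.48 ± 0.43) and Mir29a (−3.18 ± 0.55). The microRNA share was 12.2% ± 2.14 against 7.27% ± 0.46, piRNA 84.3% ± 1.95 against 90.9% and rRNA 2.86% ± 0.39 against 1.23% (exact p 0.0286, adjusted 0.0357), and each call was lost without any 1 of the 4 untreated libraries, at 4.75 to 5.06, −6.80 to −6.40 and 1.54 to 1.77 points. In all 37 RNAs rose and 86 fell. Falls were made by 4 of 4 mir-34, 6 of 8 mir-17-92 (1 rose) and 8 of 19 X-linked microRNAs (10 adjusted over the list alone). The first pair of tests held with an estimated correlation (adjusted p 0.0159 and 0.0481) and the X-linked test was lost (0.192).

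RppH in testis raised tRNA Gly-GCC by 5.20 ± 1.16 (summed, adjusted p 0.00268, n = 4 and 4), Mir141 by 3.84 ± 1.15 and Mir10b by 3.63 ± 0.69. Mir463 fell by 4.07 ± 0.45, Mir449c (−3.84 ± 0.61) and Mir34c (−3.20 ± 0.40). For microRNA the share was 19.5% ± 5.28 against 7.27% ± 0.46, piRNA 59.4% ± 31.1 against 90.9% and rRNA 9.16% ± 10.7 against 1.23% (exact p 0.0286, adjusted 0.0476), calls that were lost without any 1 of the 4 untreated libraries, at 12.1 to 12.4, −31.7 to −31.3 and 7.83 to 8.06 points. Without base RppH replicate 1, which had 45.4% tRNA, the piRNA and rRNA differences were −16.1 and 2.57 points. In all 123 RNAs rose and 83 fell. Of the lists 4 of 4 mir-34 and 7 of 19 X-linked microRNAs (10 adjusted over the list alone) fell, and 6 of 9 sperm tRNAs (8), 21 of 37 other tRNAs (26), 4 of 5 rRNA members (5) and 3 of 5 mir-200 microRNAs rose. The tRNA and mir-200 rises came mostly from base RppH replicate 1. Without it Gly-GCC rose by 1.99 ± 0.64 (summed, adjusted p 0.0158) and Mir141 did not pass (1.84 ± 0.98, adjusted p 0.148), while Mir10b rose by 4.05 ± 0.38. In the lists 2 of 9 sperm tRNAs rose and 1 fell, 1 of 38 other tRNAs rose and 5 fell, and 1 of 5 mir-200 microRNAs rose. Without it 147 of 459 piRNAs rose and 103 fell (17 and 14 of 458 with it), and of 20 X-linked microRNAs 3 rose and 11 fell. Of 7 blood microRNAs 1 rose and 4 fell (1 and 0 with it), and of 8 mir-17-92 microRNAs 2 rose and 6 fell (2 and 3), while 4 of 4 mir-34 fell and 4 of 5 rRNA members rose as before. The mir-34 test held with an estimated correlation (adjusted p 0.0244) and the others were lost (lowest p 0.0357). DESeq2 gave 367 higher and 151 lower. The calls numbered 485 without base RppH replicate 1, 124 without acid untreated 1, 128 without acid untreated 2 and 105 without base untreated 2.

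Base against acid libraries of testis (n = 10 and 10) gave 0 calls by edgeR, with an unadjusted p under 0.05 for 71 higher RNAs and 0 calls by DESeq2. For piRNA the share was 69.6% ± 24.4 and 82.6% ± 7.70 (permutation p 0.12 over all 20 libraries), a difference that was −6.75 points without base RppH replicate 1, and the microRNA share 9.66% ± 6.86 and 9.04% ± 6.64 (permutation p 0.837). Regrouped within each enzyme, a choice made after seeing the data, the p was 0.0118 for piRNA (adjusted 0.0592), 0.0422 for tRNA (5.53 points, adjusted 0.105) and 0.54 for microRNA, so no share passed. Adjusted over the list alone, 5 of 5 mir-200 microRNAs and 1 of 11 Hox list microRNAs were higher in base libraries, and 2 of 5 and 0 of 11 without base RppH replicate 1. The mir-200, sperm tRNA, other tRNA and piRNA tests passed at the preset correlation and were lost with the estimated one (lowest p 0.0279, adjusted 0.334).

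Cauda sperm and testicular sperm were compared along maturation. Crisp1 was higher in cauda sperm by 8.56 ± 1.12 (log2, adjusted p 8.75e-06, n = 7 and 4), tRNA Glu-CTC by 6.90 ± 0.55 and Gly-GCC by 6.50 ± 0.52. Mir451b was lower (−9.48 ± 0.74) and Mir486, at chromosome 8, 23142555 to 23142682 (−9.48 ± 0.68). In testicular sperm, whose titles carry different marks, Mir486 averaged 32740 CPM with an SD of 44200. For tRNA the share was 91.1% ± 4.03 against 3.85% ± 2.83, piRNA 2.70% ± 1.04 against 55.4% ± 21.9, microRNA 1.26% ± 0.68 against 14% ± 12.0 and rRNA 3.83% ± 1.95 against 25.3% ± 9.78 (exact p 0.00303, the smallest possible, adjusted 0.00455). The microRNA difference was −7.20 points without testicular sperm replicate 1. With cauda sperm of 1 source number summed, a choice made after seeing the data (n = 4 and 4), these shares still passed (exact p 0.0286, adjusted 0.0343), and 4503 RNAs were higher and 2498 lower. In all 3650 RNAs were higher and 3379 lower. Higher were 9 of 9 sperm tRNAs, 38 of 43 other tRNAs (39 adjusted over the list alone) and 7 of 13 spermatid mRNAs. Lower were 384 of 464 piRNAs (385), 4 of 4 mir-34, 20 of 20 X-linked, 9 of 9 mir-17-92, 12 of 12 let-7 and 7 of 7 blood microRNAs, 4 of 5 rRNA members and 4 of 6 Sertoli and Leydig mRNAs. With an estimated correlation all list tests were lost (lowest p 0.0215, adjusted 0.146). RLE scaling, with a median shift of 0.41, gave 4584 higher and 2764 lower, and DESeq2 4161 and 2537. In the whole sperm of cauda and testis compared above, several lists went the other way. There 10 of 12 let-7, 6 of 7 blood and 6 of 9 mir-17-92 microRNAs and 3 of 5 rRNA members were higher in cauda. X-linked microRNAs were mixed there (5 higher, 4 lower), as were mir-34 (1 and 2). The directions were alike for piRNAs (lower) and sperm tRNAs (higher). Why the lists differ was not tested.

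Cauda epididymosomes were set against testicular sperm to show what vesicle RNA would add. Crisp1 was higher in epididymosomes by 9.57 ± 1.18 (log2, adjusted p 4.89e-06, n = 3 and 4), Gpx3, a secreted glutathione peroxidase gene at chromosome 11, 54902453 to 54910377, by 7.99 ± 0.68, Mir141 by 7.73 ± 1.06 and the muscle microRNA Mir143 by 6.71 ± 0.60. Gm3893 was lower (−8.94 ± 0.67) and tRNA Ala-TGC (−3.58 ± 0.56). The tRNA share was 72.3% ± 3.48 against 3.85% ± 2.83 (exact p 0.0286, the smallest possible, adjusted 0.0857), piRNA 0.931% ± 0.015 against 55.4% ± 21.9 (exact p 0.0571) and microRNA 23.1% ± 3.02 against 14% ± 12.0 (exact p 0.257). In all 3928 RNAs were higher and 3385 lower. Higher were 11 of 11 Hox list, 5 of 5 mir-200, 5 of 5 muscle and 3 of 12 let-7 microRNAs, 9 of 9 sperm tRNAs and 34 of 43 other tRNAs. Lower were 349 of 464 piRNAs (352 adjusted over the list alone), 17 of 20 X-linked (20), 8 of 9 mir-17-92 and 5 of 7 blood microRNAs, and 8 of 13 spermatid mRNAs (10). None of the list tests held with an estimated correlation (lowest p 0.0179, adjusted 0.23).

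Epididymosomes and cauda sperm, which share the epididymal lumen, were compared directly. Mir141 was higher in epididymosomes by 6.94 ± 0.81 (log2, adjusted p 5.8e-06, n = 3 and 7), Mir143 by 6.66 ± 0.47 and Mir101a, at chromosome 4, 101346945 to 101347027, by 6.40 ± 0.45. tRNA Leu-AAG was lower (−4.11 ± 0.56), 5.8S rRNA (−3.66 ± 0.51) and the piRNA pi-Ankrd11.1 (−3.33 ± 0.49). The microRNA share was 23.1% ± 3.02 against 1.26% ± 0.68 and tRNA 72.3% ± 3.48 against 91.1% ± 4.03 (exact p 0.00833, the smallest possible, adjusted 0.025), and without any 1 of the 3 epididymosome libraries the differences were 20.1 to 22.8 and −19.8 to −16.7 points. There the smallest exact p is 0.0278, adjusted 0.0833, so the calls were lost by the number of libraries. With the source numbers of cauda sperm summed (n = 3 and 4) the differences were 21.8 and −19.3 points (exact p 0.0286, the smallest possible, adjusted 0.0857), and 598 RNAs were higher and 2044 lower. The piRNA share was 0.931% against 2.70% ± 1.04 (exact p 0.025, adjusted 0.05), and passed without cauda sperm replicate 1, 5, 6 or 7, at −1.96 to −1.53. In all 1706 RNAs were higher and 1921 lower. The epididymosome titles carry 1 suffix code that no cauda sperm title has, so the groups are split by it, and with the suffix as a term the calls numbered 1795, of which 1329 were lower. Higher were 12 of 12 let-7, 11 of 11 Hox list, 5 of 5 mir-200, 5 of 5 muscle, 2 of 2 endothelial and 7 of 7 blood microRNAs. Lower were 12 of 13 spermatid mRNAs, 5 of 9 sperm tRNAs and 213 of 464 piRNAs (219 adjusted over the list alone). No list test held with an estimated correlation (lowest p 0.00444, adjusted 0.0666). RLE scaling, with a median shift of −0.22, gave 1147 higher and 2128 lower, and DESeq2 947 and 2103.

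**Figure D2:**
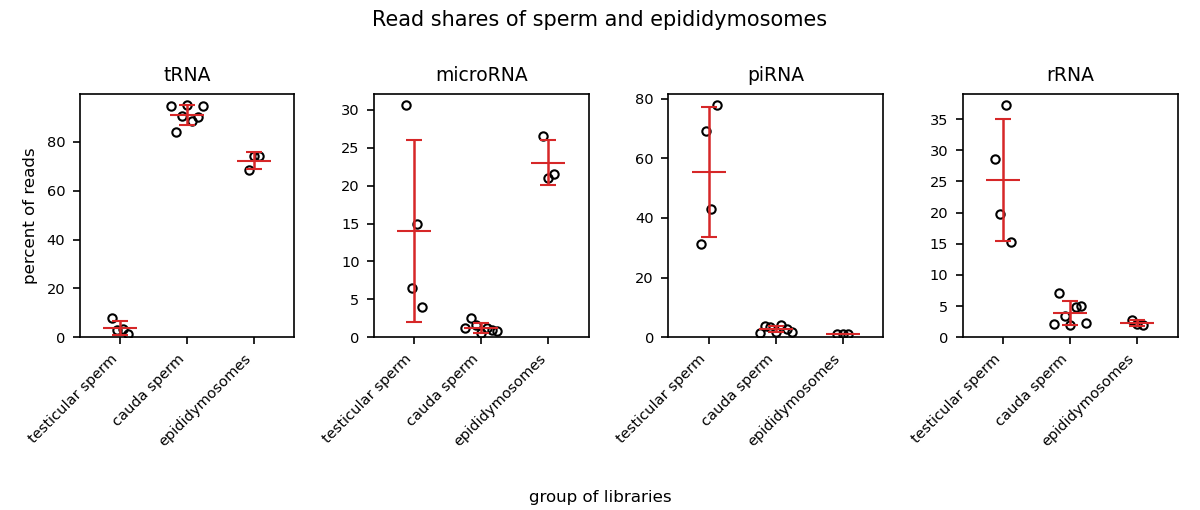
Share of reads (percent of the library) taken by each RNA class along sperm maturation. Points are libraries and bars are means with SD, and the tRNA share runs from 3.85% in testicular sperm (n = 4) to 72.3% in cauda epididymosomes (n = 3) and 91.1% in cauda sperm (n = 7).

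Testicular sperm fused with caput epididymosomes were set against a mock fusion, to ask whether vesicles can pass on RNA. Gpx5 rose by 4.76 ± 0.65 (log2, adjusted p 0.00151, n = 2 and 2), from 5.8 to 159.4 CPM. Mir200b, at chromosome 4, 156055681 to 156055750, rose by 4.41 ± 0.52, Mir10a by 4.37 ± 0.48 and Mir10b by 4.20 ± 0.53 (adjusted p 0.000877 to 0.000933). For tRNA the share was 8.81% ± 0.09 against 5.58% ± 0.21 and piRNA 25.5% ± 8.62 against 38.3% ± 2.21 (exact p 0.333, the smallest possible, so this design cannot reach 0.05). In all 404 RNAs rose and 2 fell, Gm906 (−3.26 ± 0.85) and Fbxo2 (−2.37 ± 0.66), named after their values were seen. Each fusion library shares its title suffix code with 1 mock library, and with that code as a block 709 RNAs rose and 227 fell. Rises were made by 11 of 13 epididymal mRNAs (12 adjusted over the list alone), 5 of 5 mir-200, 3 of 10 Hox list (7), 3 of 4 muscle (4), 0 of 2 endothelial (2) and 3 of 12 let-7 microRNAs (4), whose median of 0.08 was −0.03 under RLE scaling, and adjusted over the list alone 3 of 4 mir-34 microRNAs fell. With an estimated correlation all list tests were lost (lowest p 0.0522, adjusted 0.276). Without fusion replicate 1 there were 204 calls.

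4-thiouracil (4-TU) is built into new RNA and read as C in place of T. By their titles caput tissue was the positive sample, testis the negative one and cauda sperm the test (1 library each with and without 4-TU, so no test between conditions). Over 390 microRNAs the median T to C percent in caput was 0.1236 with 4-TU and 0.0534 without, in testis 0.0564 and 0.0661, and in cauda sperm 0.0627 and 0.0486. By mean the differences changed sign, to −0.105 in caput, 0.203 in testis and −0.0801 in cauda sperm. Of the microRNAs that the rule named, mir-20b-5p had 9.82% (7.68 to 12.3, exact 95% interval) against 4.90% (3.62 to 6.46) in caput. Its control value is far above the control median, so much of its T to C reading is present without 4-TU. The intervals cover counting error only. Among 79 microRNAs with at least 1000 reads in all 6 libraries, a choice made after seeing the data, the value was above the control for 77 in caput, 36 in testis and 60 in cauda sperm, and separate intervals put 56 higher in caput, 0 in cauda sperm, and 4 lower in testis. These include copies of 1 mature RNA under several names. With each of 61 mature RNAs counted once the numbers were 59, 25 and 44, and 46, 0 and 3. In caput mir-191-5p had 0.3797% (0.342 to 0.420) against 0.1358% (0.116 to 0.158). The mir-200 list's median difference in caput, 0.1402 points, was at the 99.8th percentile of 10000 random lists of like abundance, and mir-17-92 at 98.9. In testis, the negative sample, mir-200 was at 98.2 (0.0218 points), so its rank is not specific to caput. In caput mir-34 was at 1.6, and the X-linked list had medians of 0 with and without 4-TU, so it has no reading. In cauda sperm mir-200 was at 42.4 and blood at 95.8. There Hox was at 0.2, but at 26.9 with each mature RNA counted once. Those others were then at 99.6, 99.2, 97.2, 2.2, 44.4 and 97.3.

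**Figure D3:**
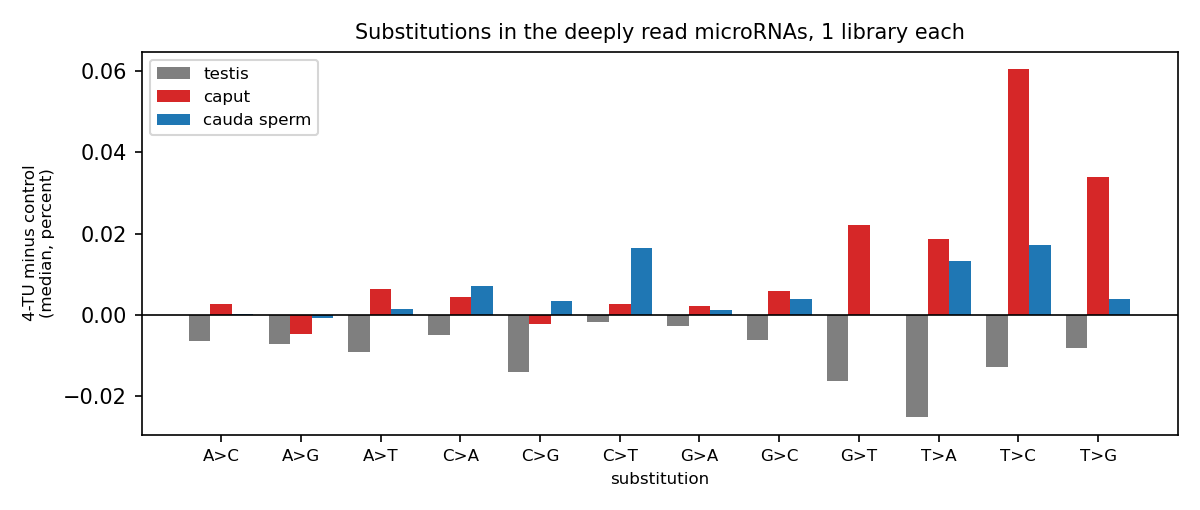
Median difference in percent of reads with each base substitution, 4-TU library minus control library, over 79 microRNAs with at least 1000 reads in all 6 libraries, in testis, caput and cauda sperm (1 library per condition). For T to C it is −0.0128, 0.0605 and 0.0173.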

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

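The tests on the microRNA fall in washed sperm, on the piRNA and mir-200 shares of the testis library and on the fusion were chosen after the results had been seen, and the correlation and Hox list tests of that library were chosen before, except for the Hox list's comparison with RppH libraries.

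Among 72 sets of shares, each of 1 class in 1 group of 4 to 10 libraries, 10 shares lay far from the others of their set, where chance gives about 1 in 20 sets. In epididymis treated with kinase lacking the 3′ phosphatase, acid replicate 2 had 3.90% tRNA. In testis, base untreated replicate 1 had 0.952% tRNA and base kinase replicate 1 had 24% rRNA. The testis library of phosphatase-free kinase, base replicate 1, had 43.8% piRNA and 54.4% rRNA. Testis base RppH replicate 1 had 13.1% piRNA, 25.2% rRNA and 45.4% tRNA. In the cauda sperm washes, low wash replicate 3 had 29.5% rRNA and mid wash replicate 5 had 42.0% tRNA.

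Differences of an effect between locations passed an interaction test. The head to tail difference of sperm differed between cauda and testis for 1704 RNAs, with pi-Ankrd11.1 at 3.81, pi-Ankrd11.2 at 3.74, Smcp at −4.54, Gm20594 at −4.09 and the piRNA 1-qD-2017.1 at −3.68. The response to kinase differed between cauda and caput sperm for 137 RNAs, with Snord88c at 4.95, Snord32a at 4.47, Crisp1 at 4.03, Mir465b-1 at −5.20, Mir465c-2 at −4.99 and Mir465b-2 at −4.81.

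The microRNA fall in washed cauda sperm was weighed against a shift by a few abundant RNAs and loss of blood cells alone. The median log2 change of microRNAs minus that of genes at the high wash was −1.42, which argues against a change of scale alone. The 313 microRNAs outside the blood list had a median of −1.36 (−0.82 to −2.31 over the 5 sets). Some may be of blood cells too. The epithelial mir-200 list had −2.77, which argues against blood cell loss alone. Whether epithelial RNA outside sperm was removed was not tested.

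The testis library base RppH replicate 1 was weighed as an epididymis library with a wrong label and as a mixture. Its microRNA profile correlated less with the other testis RppH libraries than with those of epididymis (difference −0.102, means 0.587 and 0.689), which goes with a wrong label. Its piRNA share of 13.1% was above the highest of 20 epididymis libraries, 11.8%, and of epididymis RppH libraries, 2.33%, which argues against a pure epididymis library. The mir-200 list took 5.03% of its microRNA reads, against at most 0.371% in the other 19 testis libraries and 3.19% in the 20 epididymis libraries. The Hox list took 36.8%, inside the 11.1 to 80.9% of the other 19, a bound badly chosen because this share moves several-fold with the enzyme, but below all others treated with RppH, at least 61.9% in testis and 66.1% in epididymis. A mixture lies between its sources, so both values argue against testis RNA mixed with RNA like that of these epididymis libraries. What set this library apart stays open.

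The rises after fusion were weighed against library size and for vesicle RNA in the libraries. The smallest fusion total was 0.865 of the largest mock total, which argues against more reads as the cause. Of the microRNAs higher in cauda epididymosomes than in testicular sperm, 33 rose, with a median of 1.05, against 2 of 206 others, with a median of −0.74. The set test had p 1.52e-10 at the preset correlation and 0.144 with the estimated one, so with 2 libraries a side it cannot be told apart from a chance shift of correlated microRNAs. With the title suffix code as a block 55 of the set rose and 51 of the others fell, and the p values were 1.59e-11 and 0.278, which leaves this open too. Whether vesicles fused with sperm or stuck to them may not be read from these libraries.

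Other splits of the same libraries were counted to ask whether chance can be excluded. For the low, mid and high wash 9, 352 and 199 calls stood against at most 1 in other splits. Most of these part fewer than the 5 sets, and within sets p cannot go below 0.0625, so they do not exclude chance. It can be excluded for cauda heads against tails (3540 calls, at most 1506 otherwise). In epididymis it can for kinase (747), phosphatase-free kinase (934), AlkB (366) and RppH (363), each against at most 0. In testis it can for kinase (123, at most 1), phosphatase-free kinase (456, at most 2), AlkB (123, at most 0) and RppH (206, at most 61). Along maturation it can for cauda against testicular sperm (7029, at most 818), for epididymosomes against testicular sperm (7313, at most 6413) and against cauda sperm (3627, at most 870). The splits with cauda sperm take its 7 libraries as separate units, though 6 of them share 3 source numbers. Chance is excluded there only if those libraries are independent. For the kinase response between locations 2 of 100 splits, the real one among them, had as many calls (137, and 163 at most). These splits mix cauda and caput libraries, which differ widely by location, and this adds spread, so they do not decide this. For base against acid in epididymis 2 of 100 splits had at least the 1 call, and 1 other split had 9. By that count chance is excluded, but the call was lost without any 1 of 5 libraries and with tRNA copies summed, so nothing rests on it. In testis base against acid had 0 calls, which all 100 splits match or exceed by construction (60 at most), so the count tells nothing there. For kinase in cauda sperm (915), in caput sperm (595) and for cauda against caput sperm without and with kinase (765 and 565) the splits are too few, and the highest other value was 0.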

How the results depend on the processing

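The tests without 4 testis base libraries that stood apart, those over microRNAs with at least 1000 reads, the crossed pairing in epididymis, the class shares within paired numbers or within enzymes, the summed source numbers and the mature RNAs counted once were chosen after the results had been seen. Where a value moved, the cause was not tested unless it is given. Of the values that leave out 1 library, 760 class shares kept their side of the threshold, 9 gained it and 71 lost it, 201 counts or rates stayed within 1.5 times and 33 moved, and of the named RNAs 12736 kept theirs, 127 gained it, 547 lost it and 3 reversed. Under the other alternatives 10995 named RNAs kept their side, 479 gained it, 325 lost it and 14 reversed.

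With library totals alone, calls for the low, mid and high wash numbered 80, 1101 and 338, for the location difference of heads and tails 959, for cauda against caput sperm with kinase 881, for the kinase response between locations 82, for epididymis AlkB 572, for testis kinase 30 and for testis RppH 349. For cauda against caput sperm with kinase this scaling reversed Mir200a (−0.015), Mirlet7f-1 (−1.02), Mir10b (−1.04), Mir143 (−0.22), 5S rRNA (−0.92) and a piRNA each of chromosomes 18 (−0.41) and 9 (−0.20), and for epididymis AlkB Mir449a (−1.27) and Mir878 (−0.061). RLE scaling gave 3 calls for base against acid in epididymis and 53 for testis kinase. Median shifts not given above were, with RLE, −0.16 for epididymis kinase, 0.29 for phosphatase-free kinase, 0.14 for AlkB, −0.15 for testis kinase, 0.15 for testis RppH, 0.10 for testis base, 0.20 for epididymosomes against testicular sperm and −0.10 for the fusion. With library totals they were 0.12, 1.31 and −0.53 for epididymis kinase, phosphatase-free kinase and RppH, −0.14 for testis heads, −0.15 for testis AlkB, −0.23 for cauda against testicular sperm and 0.25 for epididymosomes against cauda sperm.

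DESeq2 gave 61, 643 and 307 calls for the 3 washes, 38 for testis heads against tails, 88 for the kinase response between locations, 545 for epididymis RppH, 3 for base against acid in epididymis, 185 for testis AlkB and 518 for testis RppH. Without the filter on low counts there were 12 calls for testis heads against tails, 488 for cauda against caput sperm, 20 for the kinase response, 3 for epididymis base, 244 for testis kinase, 193 for testis AlkB and 38 for testis base. With tRNA copies summed there were 2 for testis heads, 505 for cauda against caput sperm, 61 for the kinase response, 240 and 202 for epididymis AlkB and RppH, 0 for epididymis base and 22 for testis kinase, where fewer RNAs are tested by construction. Without rRNA the kinase response had 73.

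In cauda sperm heads and tails the hypotonic libraries alone gave 2095 calls, with fewer libraries. Acid libraries alone gave 195 for testis kinase, 279 for AlkB and 443 for RppH, and in epididymis they reversed 5S rRNA under phosphatase-free kinase (−1.70) and the piRNA 5-qF-4633.2 under RppH (−0.16). Without the 4 testis base libraries the calls were 214 for kinase, 774 for phosphatase-free kinase, 569 for AlkB and 603 for RppH, and under RppH Mir881 (0.35), Mir451a (−1.98) and a piRNA of chromosome 17 (0.34) reversed. The title suffix as a term gave 1795 for epididymosomes against cauda sperm. With source numbers of cauda sperm summed that comparison had 2642 calls, and its calls on microRNA (21.8 points) and tRNA (−19.3) were lost, at the smallest p of 3 against 4 libraries, while cauda against testicular sperm had 7001.

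With the replicate number as a block the washes gave 301, 1741 and 1101 calls and caput sperm with kinase 609, and beyond what the report gives it changed no other call there by over 1.5 times. Within the 5 sets the class share calls of the washes were lost, since no p can go below 0.0625: microRNA (−9.95) at the low wash, microRNA (−10.5) and rRNA (−7.48) at the mid wash, and microRNA (−10.2), rRNA (−7.96) and tRNA (11.2) at the high wash, the differences being the same. In caput sperm with kinase the smallest p within numbers is 0.25. In the other tables, and for kinase in cauda sperm, the numbers were not taken to pair libraries, though cauda sperm are labelled like caput sperm. No blocked count is given for kinase in cauda sperm or for the kinase response between locations. The block gave 103 calls for testis heads against tails and 936 for the fusion. In testis it gave 124, 454, 124 and 204 for kinase, phosphatase-free kinase, AlkB and RppH, and in epididymis 759, 932, 373 and 368. In those tables the correlations ran from −0.487 to 0.563 in epididymis, −0.192 to 0.528 in testis and −0.0299 to 0.421 in heads and tails. In cauda sperm with and without kinase they were 0.0794 to 0.349, and the fusion had 0.173. With the epididymis numbers crossed between acid and base, the calls were 776, 936, 384 and 366 for the 4 enzymes and 1 for base.

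With rRNA out of the denominator, by construction of the share, the tRNA difference passed at the low wash (12.2 points) and was lost at the high wash (7.46). Lost were microRNA in epididymis with phosphatase-free kinase (−8.47), piRNA with AlkB (−0.734), and in testis piRNA (−3.37) and tRNA (4.95) with kinase, microRNA (−3.76) with phosphatase-free kinase and microRNA (14.1) and piRNA (−29.3) with RppH. The piRNA difference with phosphatase-free kinase in testis reversed (3.74). For epididymosomes piRNA (−71.7) and tRNA (68.6) passed against testicular sperm and piRNA (−1.87) against cauda sperm. The mean T to C difference was 0.203 in testis, −0.105 in caput and −0.0801 in cauda sperm, each reversed from the median, and over deeply read microRNAs the median difference in caput was 0.0605 (0.0619 with each mature RNA counted once). Over all 335 mature RNAs counted once it was 0.0675.

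Leaving out 1 library at a time, calls ranged from 233 to 528 for the mid wash, 122 to 189 for the high wash, 0 to 4 for testis heads, 2887 to 4482 for cauda against testis, 155 to 1736 for the location difference, 71 to 129 for the kinase response, 0 to 3 for epididymis base, 46 to 101 for testis kinase, 105 to 485 for testis RppH and 204 to 608 for the fusion. Class share calls lost in this way come partly from the number of libraries, since with 3 against 4 the exact test has 35 splits and a smallest p of 0.0286, and with 2 against 7 it has 36 and 0.0278. Under testis RppH, Mir881 ranged from −0.35 to 0.37, Mir451a from −2.04 to 0.96 and that piRNA of chromosome 17 from −0.39 to 0.35. The tRNA difference ranged from 8.63 to 12.4 points at the low wash, 8.64 to 13.5 at the mid wash and 8.60 to 13.3 at the high wash. In epididymis with phosphatase-free kinase piRNA ranged from 5.58 to 8.26 and tRNA from −13.7 to −9.81, and with AlkB microRNA from 6.96 to 11.7, piRNA from −0.778 to −0.565, rRNA from −2.36 to −1.52 and tRNA from −8.53 to −4.65. In testis with kinase microRNA ranged from −2.67 to −1.61, piRNA from −13.7 to −4.94, rRNA from 4.29 to 10.6 and tRNA from 2.25 to 4.93. With AlkB there microRNA ranged from 3.97 to 5.67, piRNA from −7.32 to −5.74 and rRNA from 1.45 to 1.77, and with RppH microRNA from 10.6 to 14.1, piRNA from −38.4 to −16.1 and rRNA from 2.57 to 9.96. For epididymosomes against cauda sperm microRNA ranged from 20.1 to 22.8, piRNA from −1.96 to −1.53 and tRNA from −19.9 to −16.7.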

Other observations

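Caput sperm of the maturation series, 1 library of 13382337 reads, had 73.0% tRNA (72.97 to 73.01, exact 95% interval of counting error) and 14.1% microRNA (14.07 to 14.11). Early round spermatids had 94.2% piRNA, late round spermatids 93.7% and primary spermatocytes 93.8%, each in 1 library with no test between them. These libraries entered no comparison.

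In the 4-TU libraries the T to C difference was ranked among the 12 substitutions. By the median over all microRNAs it ranked 1 in caput, 6 in cauda sperm and 3 in testis. Over the deeply read ones it ranked 1, 1 and 9. There caput had 0.0605 points, against 0.034 for T to G, the next. Cauda sperm had 0.0173, against 0.0166 for C to T and 0.0132 for T to A, so its first rank was a near tie. In caput the let-7 list was at the 19.3rd percentile of random lists and muscle at 0.6 (19.8 and 1.2 with copies counted once). In cauda sperm mir-191-5p had 0.392% with 4-TU and 0.318% without (19147 and 9748 reads, overlapping intervals). No hypothesis beyond those weighed above was tested.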
